A study of Mus musculus with 16 samples.

How the data were processed

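Gene expression was measured in white fat of diet-induced obese mice on single-colour Illumina MouseRef-8 bead arrays, in wild-type (WT) mice (c57b6/sv129 mixed background) and in mice lacking Fgf21 (Fgf21-KO), each given vehicle or rosiglitazone. The 16 arrays form 4 groups of 2 pools, each pool holding RNA of 2 mice and hybridised to 2 arrays. The pool was the unit of replication (n = 2 pools per group) and the 2 arrays of a pool were technical repeats. Groups, pools and repeats were read from the sample titles.

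The deposited non-normalized table gives, per the file headers, the mean bead signal (intensity on a linear scale), a detection p-value, the bead standard error and the number of beads for each probe and array. The authors' deposited normalized table holds intensities on a linear scale, and its values show quantile normalization without background subtraction, since equally ranked values differ between arrays by a median of 0.109% and by 3.84% at most, while each array keeps its rank order apart from near ties. The deposited series matrix holds the same intensity values, with a largest difference of 0. A deposited statistics table gives the authors' group mean intensities, ratios of group means and p-values of the VAMPIRE test with a Bonferroni threshold of 0.05, taken over all 4 arrays of a group. The 64 columns not used were the bead standard errors of both tables and the detection p-values and bead numbers repeated in the normalized one.

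Of 25697 probes, 23978 carried a gene symbol, and 23962 of these were matched by Entrez gene ID. The main values were made from the non-normalized signals in R 4.3.3 with limma 3.58.1. Signals were background-corrected with the normexp model by way of the detection p-values (nec, offset 16), quantile normalized, put on the log2 scale, and averaged over the 2 arrays of each pool (avearrays). Probes with a detection p of 0.05 or less on at least 4 of the 16 arrays were kept, which left 13759 probes of 9543 genes, 789 of the probes without a symbol. No array was a copy of another.

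Median signals of the arrays ran from 144.9 to 192.3, and 47.6% to 51.0% of the probes were detected per array. Each signal rested on a mean of 36.0 to 38.9 beads on the WT arrays and 39.4 to 40.7 on the Fgf21-KO arrays, without overlap. The reason for this was not tested. A chip or run that goes with genotype could not be told apart from genotype here. Precision is limited by the 2 pools of each group.

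One linear model with 4 group means was fitted per probe (lmFit and eBayes, without trend or robust fitting), with 7 contrasts: rosiglitazone in each genotype, genotype under each treatment, the interaction, and the averages over genotypes and over treatments. The residual degrees of freedom were 4 and the prior added 2.75. All tests were two-sided, and limma's p-values were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. SE is the standard error of the log2 difference from this fit. Differences are written Fgf21-KO minus WT or rosiglitazone minus vehicle. Across genes, the responses of the genotypes were compared by Pearson's r, Spearman's rho and a total least squares slope, with no p-value, since genes are not independent replicates.

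Gene lists (24, of adipocyte pathways, cell types other than adipocytes, inflammation, the clock, the cell cycle, stress, and genes next to Fgf21) were tested where at least 5 genes were tested, which 22 were. Each gene stood in by its brightest probe. The test was limma's camera on moderated statistics with a preset correlation of 0.01, adjusted over lists within a contrast, with camera under an estimated correlation and fry beside it. Fry asks whether the genes of a list move, on balance, one way, and compares no list with other genes. Counts adjusted over the list alone came from Benjamini-Hochberg within a list.

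The contrasts, tests, thresholds, 24 lists, most alternatives and the choice of named genes were set before the data were examined. Named genes were to be the 8 largest rises and 8 largest falls past the threshold without overlap of pools in each of the 4 group comparisons, and likewise for the interaction without that condition. Per list they were the 4 largest changes past the threshold or, where none passed, the 2 members of smallest p, given as values. Fgf21 and a panel of 21 genes of adipocytes, inflammation and matrix, Fgf21 included, were to be named always, and 19 of the 21 were tested. Added afterwards were 4 lists (smooth muscle, liver, epithelium and ciliated cells), a fit without the pools that stood apart, and a fit with pool weights.

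The alternatives changed the background correction, its offset, the scaling, the source of the values, the probe filter, the handling of technical repeats, the variance model, the groups in the fit, a term for replicate number, the list test and the probe standing for a gene, and left out each pool in turn. The number of calls was recounted over all 35 splits of the 8 pools into 4 and 4. A block by array chip was not run, because no chip was given. Cd68 had no probe on the array and the 3 probes of Nnt were too dim to be tested.

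The model was also tested on simulated data: 200 of the 13759 probes were shifted in simulated pools, in 10 runs for each size. In rosiglitazone in WT, 0% of 2-fold, 87.2% of 4-fold and 95.8% of 8-fold changes were called. Over 4 pools per side, for the genotype averaged over treatments, these shares were 63.7%, 94.2% and 98.0%. False calls made up 0% to 6.15% of the calls. The simulated pools shared 1 variance per probe, and probes varied independently of each other. In the data the SD between pools was 0.475 in WT rosiglitazone, against 0.198 to 0.285 in the other groups. These shares may therefore not hold for comparisons that include WT rosiglitazone.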

Results

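Epididymal white fat of obese mice was profiled after 10 weeks of high-fat diet, with vehicle or rosiglitazone at 10 mg/kg given for the last 2 weeks. Rosiglitazone is an agonist of PPARG, the nuclear receptor that drives adipocyte gene expression, and FGF21 is a hormone made by liver and fat. The groups were WT vehicle, WT rosiglitazone, Fgf21-KO vehicle and Fgf21-KO rosiglitazone, with 2 pools each. Median array signals were 174 to 184 in WT vehicle, 181 to 192 in WT rosiglitazone, 147 to 152 in Fgf21-KO vehicle and 145 to 179 in Fgf21-KO rosiglitazone. Between 12234 and 13096 probes were detected per array.

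Fgf21 was detected on all 4 arrays of WT vehicle and of WT rosiglitazone, and on 1 of 4 arrays in each Fgf21-KO group. Its single probe (ILMN_2710698) had signals of 319 to 358 in WT vehicle and 288 to 560 in WT rosiglitazone, against 129 to 155 and 129 to 168 in the Fgf21-KO groups. On the log2 scale the means were 7.66 ± 0.18 (SD, n = 2) and 7.77 ± 0.84 in WT, and 5.38 ± 0.29 and 5.38 ± 0.23 in Fgf21-KO. The genotype difference was -2.28 (SE 0.38) under vehicle and -2.39 (SE 0.38) under rosiglitazone, with limma adjusted p = 0.394 and 0.1001. Averaged over treatments it was -2.34 (SE 0.27, adjusted p = 0.0684), and every Fgf21-KO pool lay below every WT pool. Between rosiglitazone and vehicle Fgf21 differed by 0.11 (SE 0.38) in WT and 0.00 (SE 0.38) in Fgf21-KO, neither past the threshold. The size depended on the background step, at -1.69 with an offset of 50 and -1.09 without correction. Whether the probe lies in the deleted part of the gene is not known from the data.

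**Figure D1:**
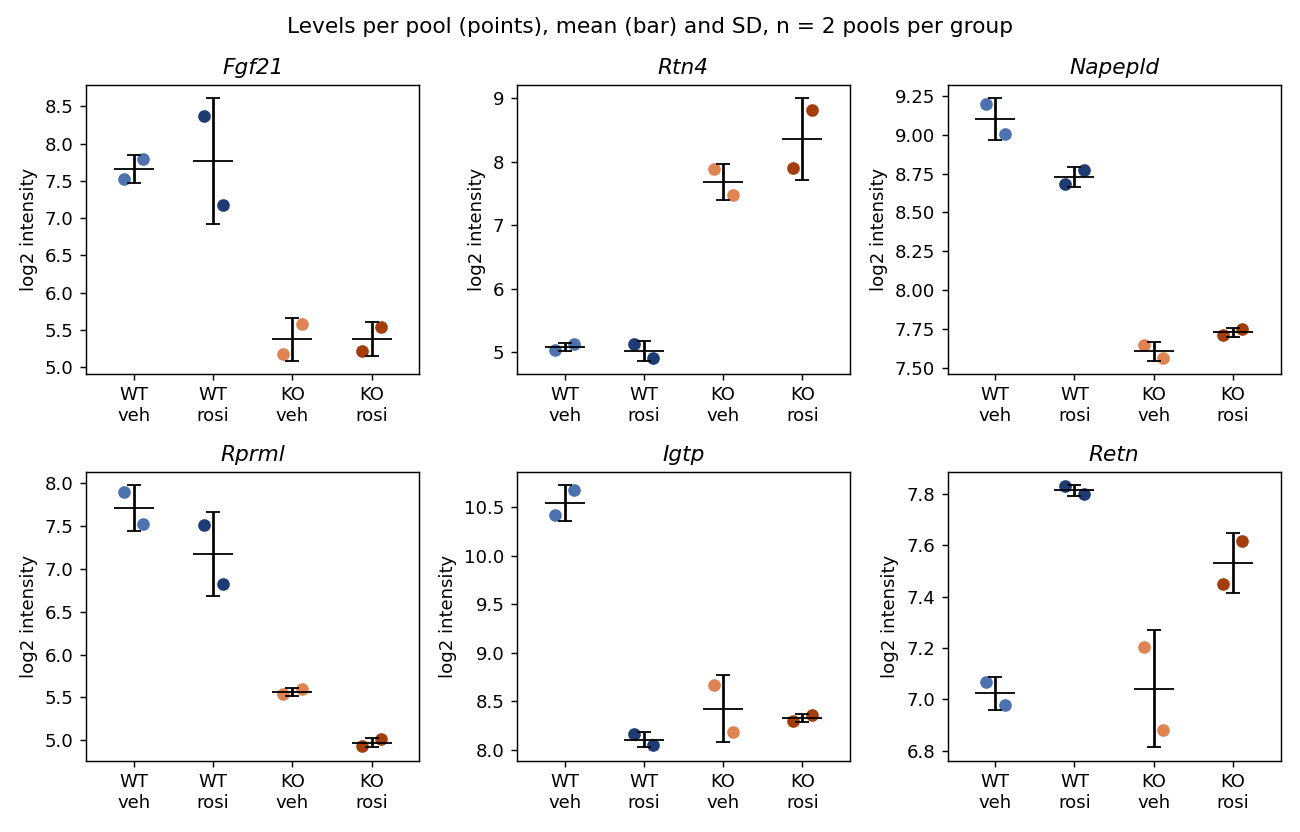
Log2 signal of Fgf21, Rtn4, Napepld, Rprml, Igtp and Retn in each of the 8 pools (points), with the group mean and SD (bar, n = 2) on the vertical axis and the 4 groups on the horizontal axis. Fgf21 means were 7.66 and 7.77 in the WT groups and 5.38 in both Fgf21-KO groups.

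The pools differed in the cell type markers they carried. In WT rosiglitazone replicate 1, smooth muscle markers lay 2.28 (log2, list median) above the mean of the other 7 pools and epithelium markers 1.74 above, with epithelium at 0.60 in WT rosiglitazone replicate 2. Liver markers lay 3.35 above in Fgf21-KO vehicle replicate 2, and ciliated cell markers 2.44 above in WT rosiglitazone replicate 2. These 4 lists were written after the values were seen. Their p-values below come from the same arrays and were adjusted over these 4 lists only. They describe the shift and are no separate support for it. Mesothelium markers, fixed beforehand, lay at -1.19 in Fgf21-KO rosiglitazone replicate 2. The first principal component held 48.2% of the variance and placed WT rosiglitazone replicate 1 at 68.5, with the other 7 pools between -16.8 and -0.298. The SD between pools was 0.475 in WT rosiglitazone, against 0.225 in WT vehicle, 0.285 in Fgf21-KO vehicle and 0.198 in Fgf21-KO rosiglitazone.

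**Figure D2:**
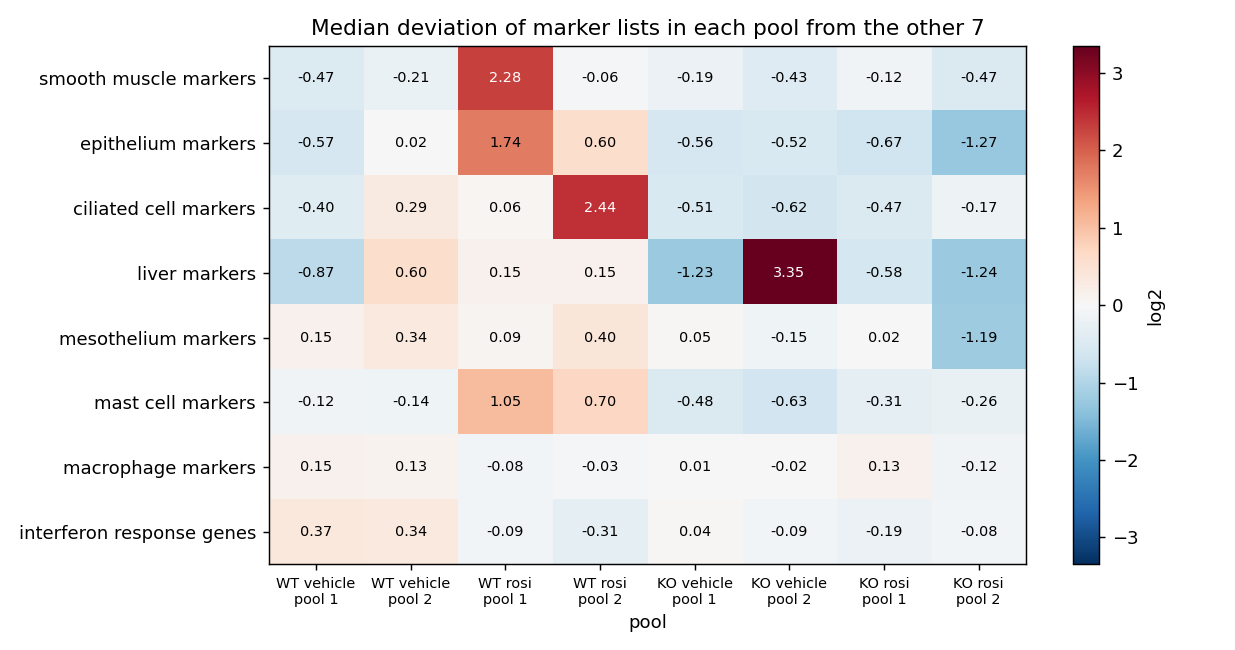
Median log2 deviation of 8 marker lists (vertical axis) in each pool from the mean of the other 7 pools (horizontal axis, 8 pools), as colour and number. Smooth muscle markers stood at 2.28 in WT rosiglitazone replicate 1 and liver markers at 3.35 in Fgf21-KO vehicle replicate 2.

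The first comparison asked how fat of obese WT mice responded to rosiglitazone. Mast cell markers rose as a group: all 7 tested genes were higher, with a median log2 difference of 0.77 (camera adjusted p = 1.01e-11, adjusted p = 0.171 with an estimated correlation). Tpsb2 and Mcpt4, proteases of mast cell granules, had values of 1.11 (SE 0.16) and 0.92 (SE 0.13). Interferon response genes fell as a group, with 10 of 12 lower and a median of -0.47 (adjusted p = 5.11e-09, adjusted p = 0.155 with an estimated correlation). Gbp3, an interferon-induced GTPase, stood at -1.27 (SE 0.13) and Ifit2 at -0.58 (SE 0.13). The WT vehicle pools carried the highest levels of this list, with medians 0.37 and 0.34 above the other 7 pools. The WT rosiglitazone pools lay at -0.09 and -0.31, and the untreated Fgf21-KO pools at 0.04 and -0.09. Inflammatory cytokines and acute phase genes fell, with 14 of 17 lower and a median of -0.36 (adjusted p = 5.37e-04, adjusted p = 0.462 with an estimated correlation). Among them the acute phase gene Saa3 had a value of -1.91 (SE 0.48) and the chemokine Ccl9 one of -0.38 (SE 0.14). Macrophage markers fell with a median of -0.21, 15 of 21 being lower (adjusted p = 0.0214, adjusted p = 0.462 with an estimated correlation), with Aif1 at -0.69 (SE 0.15) and Cd14 at -0.42 (SE 0.18). Larger medians were those of lists written afterwards: epithelium 1.54 (adjusted p = 5.04e-13, adjusted p = 0.139 with an estimated correlation), smooth muscle 1.22 (7.90e-05, 0.328) and ciliated cells 0.93 (0.00322, 0.328).

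Metabolic lists did not pass in WT. The median was 0.22 for fatty acid and triglyceride synthesis (adjusted p = 0.0671), 0.30 for brown and beige adipocyte genes (0.0992), 0.10 for oxidative phosphorylation (0.104), 0.17 for beta-oxidation (0.155), 0.17 for the tricarboxylic acid cycle (0.346) and 0.05 for PPARG targets (0.449). Retn, which encodes the adipokine resistin, was higher by 0.79 (SE 0.16, adjusted p = 0.409) and Fasn, the fatty acid synthase, by 0.90 (SE 0.26, adjusted p = 0.541). The thioesterase Acot1 stood at 2.27 (SE 0.26) and the desaturase Fads2 at 1.95 (SE 0.59). Among genes of thermogenic fat, Ucp1 had a value of 0.44 (SE 0.37), Cidea 0.46 (SE 0.29) and Acot11 0.72 (SE 0.21). The lipid handling genes Fabp4, Pck1 and Cd36 had values of 0.25, 0.36 and 0.09, with Adipoq at -0.17 and Lep at 0.04. The probes of Fabp4 and Cd36 were dim, with group means of 5.29 to 6.27 and 5.88 to 6.21. The median of all probes was 5.59 on each array. Neither probe was detected on every array, so small differences at them say little about these genes. The glucose transporter gene Slc2a4 stood at -0.43 (SE 0.33), Fgfr1 at -0.50 (SE 0.45) and the chemokine gene Ccl2 at -0.56 (SE 0.27).

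By limma, 0 probes passed for rosiglitazone in WT, where 1143 had an unadjusted p under 0.05 (616 higher, 527 lower, 688 by chance) and 1 had an adjusted p of 0.1 or less. That probe was for Igtp, an interferon-inducible GTPase, at -2.44 (SE 0.19, adjusted p = 0.0864), lower in both treated pools and chosen after its values were seen. Its mean was 10.55 in WT vehicle, against 8.10 in WT rosiglitazone, 8.43 in Fgf21-KO vehicle and 8.33 in Fgf21-KO rosiglitazone. WT vehicle thus stood apart from untreated Fgf21-KO fat as well. Adjusted over the list alone, 6 mast cell, 4 interferon, 1 PPARG target, 1 beta-oxidation, 1 adipokine and 1 skeletal muscle gene passed. Fry kept mast cell (adjusted p = 0.0190) and interferon genes (0.0337). The WT rosiglitazone pools decided the counts: 1 probe passed without replicate 1 of that group and 2702 without replicate 2, with the lone pool assumed to vary like the others. Without WT rosiglitazone replicate 2 only the mast cell call stayed, and the macrophage call was also lost without WT rosiglitazone replicate 1 or WT vehicle replicate 1.

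In Fgf21-KO mice the same question concerned the response without the hormone. Oxidative phosphorylation genes rose as a group, all 48 tested members being higher, with a median of 0.25 (adjusted p = 5.20e-13, adjusted p = 0.243 with an estimated correlation). Ndufb9 of respiratory complex I stood at 0.77 (SE 0.18) and Atp5o of the ATP synthase at 0.56 (SE 0.15). Beta-oxidation genes rose, 21 of 22 being higher (median 0.36, adjusted p = 8.32e-08, adjusted p = 0.345 with an estimated correlation), with Acadvl at 0.54 (SE 0.15) and Etfb at 0.45 (SE 0.14). PPARG targets rose with 19 of 28 higher (median 0.22, adjusted p = 1.05e-06, adjusted p = 0.345 with an estimated correlation). The fatty acid transporter Slc27a1 had a value of 1.11 (SE 0.18) and the fatty acid binding protein gene Fabp5 one of 1.16 (SE 0.23). Tricarboxylic acid cycle genes rose, 18 of 19 being higher (median 0.27, adjusted p = 2.41e-06, adjusted p = 0.346 with an estimated correlation), with Sdhd at 0.72 (SE 0.23). Brown and beige adipocyte genes rose, 9 of 11 being higher (median 0.41, adjusted p = 0.0105, adjusted p = 0.679 with an estimated correlation), with Slc25a20 at 0.53 (SE 0.17) and Ppargc1a, a coactivator of mitochondrial genes, at 0.48 (SE 0.22).

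Mesothelium markers fell in Fgf21-KO, 13 of 14 being lower (median -0.54, adjusted p = 3.09e-04, adjusted p = 0.622 with an estimated correlation), with Krt19 at -0.83 (SE 0.33) and Gpm6a at -0.70 (SE 0.27). Mast cell markers rose with all 7 higher (median 0.17, adjusted p = 0.0364, adjusted p = 0.554 with an estimated correlation), with Tpsab1 at 0.49 (SE 0.21). Genes next to Fgf21 on chromosome 7 rose with 24 of 32 higher (median 0.13, adjusted p = 0.0433, adjusted p = 0.679 with an estimated correlation), with the enzyme genes Hsd17b14 at 0.51 (SE 0.18) and Bcat2 at 0.37 (SE 0.16). Liver markers, high in 1 vehicle pool, had a median of -1.82. Panel genes included Ucp1 at 0.75 (SE 0.37), Cidea at 0.47 (SE 0.29), Retn at 0.49 (SE 0.16), Slc2a4 at 0.42 (SE 0.33), Fabp4 at 0.28 (SE 0.28), Adipoq at 0.20 (SE 0.12), Cd36 at -0.33 (SE 0.17) and the desaturase Scd1 at -0.37 (SE 0.12, adjusted p = 0.827). Klb, the FGF21 co-receptor, stood at 0.27 (SE 0.19).

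By limma, 0 probes passed for rosiglitazone in Fgf21-KO, where 775 had an unadjusted p under 0.05 (390 higher, 385 lower, 688 by chance) and the lowest adjusted p was 0.671. Adjusted over the list alone, 4 PPARG targets passed, and fry kept 0 lists (oxidative phosphorylation, adjusted p = 0.0527). Without Fgf21-KO rosiglitazone replicate 2 the mesothelium median was -0.02 and that call was lost, as was the brown and beige call there and without Fgf21-KO vehicle replicate 1. The mast cell call was lost without any 1 of the 4 Fgf21-KO pools, and the chromosome 7 call under 13 of 16 alternatives.

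Under vehicle, the genotype comparison asked what loss of Fgf21 changed in obese fat. Interferon response genes were lower in Fgf21-KO as a group, 11 of 12 of them (median -0.28, adjusted p = 6.24e-08, adjusted p = 0.186 with an estimated correlation). Gbp3 stood at -1.23 (SE 0.13) and the antiviral gene Oasl2 at -0.95 (SE 0.24). Both WT vehicle pools carried the higher levels, with list medians 0.37 and 0.34 above the other 7 pools. Mast cell markers were lower, 6 of 7 of them (median -0.42, adjusted p = 7.15e-04, adjusted p = 0.438 with an estimated correlation), with the chymase gene Cma1 at -0.42 (SE 0.15) and Mcpt4 at -0.37 (SE 0.13). Genes of fatty acid and triglyceride synthesis were higher, 16 of 20 of them (median 0.15, adjusted p = 0.00127, adjusted p = 0.438 with an estimated correlation). The lipogenic regulator Thrsp had a value of 0.63 (SE 0.14) and the acetyl-CoA synthetase gene Acss2 one of 0.60 (SE 0.22). Extracellular matrix genes were higher, 19 of 26 of them (median 0.17, adjusted p = 0.0374, adjusted p = 0.991 with an estimated correlation), with the collagen genes Col6a2 at 0.71 (SE 0.16) and Col4a2 at 0.46 (SE 0.16). Liver markers, a list written afterwards, had a median of 1.05 (adjusted p = 1.53e-06, adjusted p = 0.881 with an estimated correlation), from the 1 pool in which they were high.

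Clock genes had a median of -0.16 under vehicle (adjusted p = 0.0546), with the clock-controlled factor Dbp, which also lies next to Fgf21, at -1.03 (SE 0.25) and Per2 at -0.74 (SE 0.19). Panel values included Fabp4, a fatty acid binding protein gene of adipocytes, at -0.73 (SE 0.28), its probe detected on 4 of 4, 4 of 4, 0 of 4 and 2 of 4 arrays of WT vehicle, WT rosiglitazone, Fgf21-KO vehicle and Fgf21-KO rosiglitazone. Fasn stood at 0.57 (SE 0.26), Ccl2 at 0.35 (SE 0.27), Cd36 at 0.34 (SE 0.17), Angptl4 at 0.28 (SE 0.17) and Col1a1 at 0.29 (SE 0.23). Pparg stood at -0.18 (SE 0.18), Klb at 0.11 (SE 0.19) and the macrophage gene Adgre1 at -0.10 (SE 0.13). By limma, 0 probes passed for genotype under vehicle, where 655 had an unadjusted p under 0.05 (320 higher, 335 lower, 688 by chance) and the lowest adjusted p was 0.108. Adjusted over the list alone, 2 interferon genes, 5 clock genes (4 lower, 1 higher) and 1 FGF21 receptor response gene passed, and fry kept interferon genes (adjusted p = 0.0349). The synthesis call was lost without WT vehicle replicate 2 or Fgf21-KO vehicle replicate 1, and the matrix call without WT vehicle replicate 1 or Fgf21-KO vehicle replicate 1.

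Under rosiglitazone, the genotypes were compared in drug-treated fat. Mast cell markers were lower in Fgf21-KO, all 7 of them (median -0.997, adjusted p = 5.48e-10, adjusted p = 0.453 with an estimated correlation), with Mcpt4 at -0.997 (SE 0.13) and Tpsb2 at -1.07 (SE 0.16). Mesothelium markers were lower, 12 of 14 of them (median -0.67, adjusted p = 6.07e-05, adjusted p = 0.525 with an estimated correlation). Their members of smallest p, the keratin genes Krt8 at -2.34 (SE 0.30) and Krt18 at -2.72 (SE 0.51), are also expressed in other epithelia, and the epithelium markers had a median of -1.86 (adjusted p = 1.65e-15, adjusted p = 0.141 with an estimated correlation). Of the other lists written afterwards, smooth muscle markers had a median of -1.14 (adjusted p = 0.0196) and ciliated cell markers -1.29 (0.00975), each with adjusted p = 0.532 with an estimated correlation, and liver markers -0.72 (0.435). PPARG targets were higher, 21 of 28 of them (median 0.19, adjusted p = 0.00191, adjusted p = 0.525 with an estimated correlation), with Slc27a1 at 1.02 (SE 0.18) and the lipid droplet gene Plin2 at 0.75 (SE 0.14). Inflammatory genes were higher (median 0.28, 11 of 17), as were endothelial markers (median 0.15, 11 of 16), each with adjusted p = 0.0338 and adjusted p = 0.525 with an estimated correlation. Ccl2, which recruits monocytes, stood at 1.08 (SE 0.27), the acute phase lipocalin gene Lcn2 at -2.51 (SE 0.56), and the endothelial genes Cdh5 and Pecam1 at 0.84 (SE 0.26) and 1.29 (SE 0.44). Oxidative phosphorylation genes passed as higher by camera with adjusted p = 0.0338 (adjusted p = 0.525 with an estimated correlation), while their median was 0.00 and 24 of 48 were higher.

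Among panel genes under rosiglitazone, Slc2a4 stood at 0.85 (SE 0.33), Fabp4 at -0.70 (SE 0.28), Pck1 at -0.68 (SE 0.36), Fgfr1 at 0.68 (SE 0.45), Klb at 0.52 (SE 0.19), Scd1 at -0.39 (SE 0.12) and Retn at -0.28 (SE 0.16). The beta-oxidation member Acot1 stood at -2.57 (SE 0.26) and the elongase gene Elovl6 at -1.24 (SE 0.24). By limma, 0 probes passed for genotype under rosiglitazone, where 2182 had an unadjusted p under 0.05 (1067 higher, 1115 lower), 59 had an adjusted p of 0.1 or less (13 higher, 46 lower) and the lowest adjusted p was 0.0673. In the lists named above, 6 mast cell, 4 mesothelium, 2 PPARG target, 3 inflammatory (2 higher, 1 lower), 0 endothelial and 1 oxidative phosphorylation gene passed when adjusted over the list alone, and fry kept mast cell markers (adjusted p = 0.0117). Without WT rosiglitazone replicate 1, 60 probes passed, against 3391 without replicate 2, 1 when either WT vehicle pool was left out, and 57 with median scaling, 52 of them lower. Without WT rosiglitazone replicate 2 only the mast cell call stayed and the oxidative phosphorylation median was -0.07, and the PPARG target and oxidative phosphorylation calls were also lost without Fgf21-KO rosiglitazone replicate 2. The endothelial call was kept in 10 of 16 alternatives, being lost without WT rosiglitazone replicate 1 or Fgf21-KO rosiglitazone replicate 2 as well, and the inflammatory call in 7 of 16. Over the alternatives the mesothelium median ran from -1.17 without Fgf21-KO rosiglitazone replicate 1 to -0.27 without replicate 2 of that group.

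The interaction tested whether the rosiglitazone response itself differed between genotypes, as Fgf21-KO response minus WT response. Interferon response genes responded more positively in Fgf21-KO (median 0.28, 10 of 12 above 0, adjusted p = 3.34e-04, adjusted p = 0.482 with an estimated correlation), with Gbp3 at 1.42 (SE 0.18). Their median response was -0.47 in WT and -0.03 in Fgf21-KO. Both WT vehicle pools stood highest, with list medians 0.37 and 0.34 above the other pools. Mast cell markers responded more negatively, all 7 of them (median -0.63, adjusted p = 3.34e-04, adjusted p = 0.488 with an estimated correlation), with Tpsb2 at -0.94 (SE 0.22). Oxidative phosphorylation genes responded more positively, 37 of 48 of them (median 0.13, adjusted p = 0.00249, adjusted p = 0.488 with an estimated correlation), with Atp5o at 0.66 (SE 0.21). PPARG targets did so with a median of 0.11 (adjusted p = 0.0132, 0.488 with an estimated correlation), beta-oxidation genes with 0.27 (0.0374, 0.488) and tricarboxylic acid cycle genes with 0.13 (0.0374, 0.545). Slc27a1 stood at 0.90 (SE 0.26), Plin2 at 0.60 (SE 0.19) and Acadl at 1.03 (SE 0.42). Of 22 beta-oxidation genes, 18 responded more positively and 4 more negatively. Among these 4 was Acot1, with means of 6.67 and 8.94 in WT vehicle and WT rosiglitazone. In Fgf21-KO its means were 6.81 and 6.37. The medians of endothelial markers and inflammatory genes were 0.16 and 0.18 (adjusted p = 0.0374 and 0.0419, adjusted p = 0.490 and 0.545 with an estimated correlation). Genes of fatty acid and triglyceride synthesis responded more negatively (median -0.23, 15 of 20, adjusted p = 0.00890, adjusted p = 0.488 with an estimated correlation), with Elovl6 at -1.41 (SE 0.33) and Thrsp at -0.61 (SE 0.20). Mesothelium markers did too (median -0.40, 12 of 14, adjusted p = 0.00890, adjusted p = 0.545 with an estimated correlation), with Krt8 at -1.77 (SE 0.42) and Krt18 at -2.47 (SE 0.72). Of the lists written afterwards, epithelium markers had a median of -1.67 (adjusted p = 1.16e-12, adjusted p = 0.135 with an estimated correlation), liver markers -1.64 (4.78e-05, 0.340), smooth muscle markers -1.25 (0.00400, 0.340) and ciliated cell markers -0.90 (0.00692, 0.340).

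By limma, 0 probes passed for the interaction, where 681 had an unadjusted p under 0.05 (314 above 0, 367 below) against 688 by chance, and the lowest adjusted p was 0.502. Of the panel, Slc2a4 stood at 0.85 (SE 0.47), Ccl2 at 0.73 (SE 0.38), Fasn at -0.73 (SE 0.36), Adipoq at 0.38 (SE 0.17) and Klb at 0.42 (SE 0.26), none past the threshold. Adjusted over the list alone, 2 mast cell genes (below 0), 1 interferon gene (above 0) and 1 beta-oxidation gene passed, and fry kept 0 lists. The beta-oxidation gene lay below 0, against the direction of its list. Across 9543 genes the responses of the genotypes had a correlation of r = 0.0493 (rho 0.0939, slope 0.0863), from -0.0242 to 0.123 when 1 pool was left out. Without WT rosiglitazone replicate 2, 1702 probes and 0 of the 10 lists passed. Without Fgf21-KO rosiglitazone replicate 2 the mesothelium median was 0.02, and of 16 alternatives the oxidative phosphorylation, mast cell and interferon calls were each kept in 13, fatty acid synthesis and mesothelium in 11, PPARG targets in 10, beta-oxidation and tricarboxylic acid cycle in 9, and endothelial and inflammatory genes in 6.

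**Figure D3:**
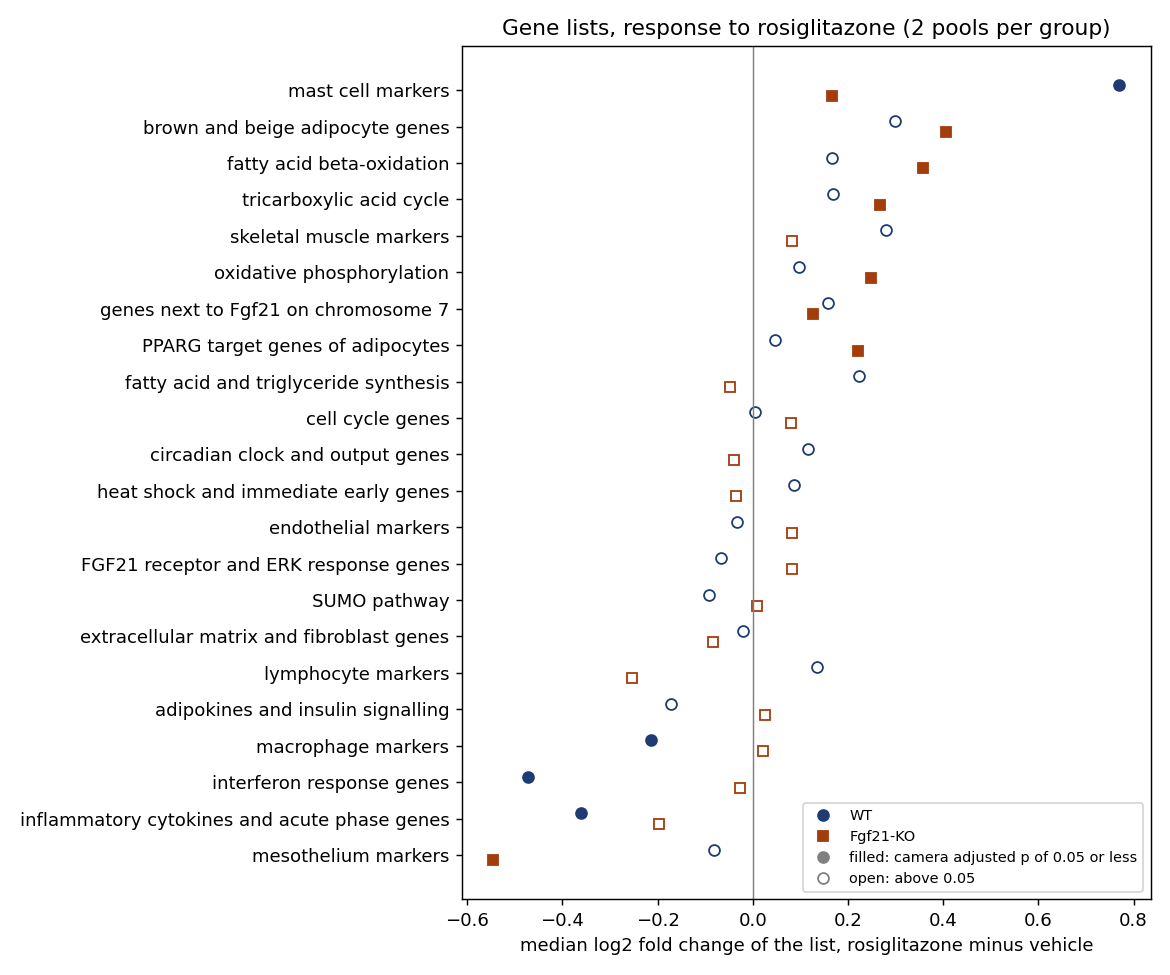
Median log2 difference, rosiglitazone minus vehicle (horizontal axis), of 22 gene lists (vertical axis) in WT (circles) and Fgf21-KO (squares), filled where camera's adjusted p was 0.05 or less. Mast cell markers stood at 0.77 in WT and 0.17 in Fgf21-KO, and oxidative phosphorylation genes at 0.10 and 0.25.

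Averaged over genotypes, rosiglitazone raised oxidative phosphorylation genes (median 0.17, 44 of 48 higher, adjusted p = 1.04e-08, adjusted p = 0.166 with an estimated correlation) and mast cell markers (median 0.45, 7 of 7, adjusted p = 3.98e-10, adjusted p = 0.166 with an estimated correlation). Both were also kept by fry (adjusted p = 0.0181 each). Beta-oxidation genes rose with a median of 0.26 (adjusted p = 7.80e-06, adjusted p = 0.327 with an estimated correlation), tricarboxylic acid cycle genes with 0.19 (2.68e-04, 0.362), PPARG targets with 0.15 (4.51e-04, 0.362), brown and beige genes with 0.29 (0.00196, 0.422) and genes next to Fgf21 with 0.13 (0.0322, 0.524). These metabolic lists passed in Fgf21-KO but not in WT. The WT medians were above 0, at 0.10 for oxidative phosphorylation (camera adjusted p = 0.104) and 0.05 for PPARG targets (0.449). Interferon genes fell with a median of -0.20 (adjusted p = 1.95e-06, adjusted p = 0.166 with an estimated correlation) and inflammatory genes with -0.28 (8.82e-04, 0.362). In Fgf21-KO alone, interferon genes had a median of -0.03 with 6 of 12 lower (camera adjusted p = 0.427). Their averaged fall thus rests on WT, where both vehicle pools stood high. The same WT vehicle pools enter the genotype and interaction calls of this list, so these calls are not separate results. The lists written afterwards had medians of 0.68 for epithelium (adjusted p = 9.23e-05), 0.61 for smooth muscle (0.00197), -0.84 for liver (0.00651) and 0.47 for ciliated cells (0.0470), each with adjusted p = 0.430 with an estimated correlation. Retn stood at 0.64 (SE 0.11, adjusted p = 0.432), Fabp5 at 0.88 (SE 0.17), Ucp1 at 0.59 (SE 0.26), Cidea at 0.47 (SE 0.20), Ppargc1a at 0.47 (SE 0.15) and Saa3 at -1.24 (SE 0.34). By limma, 0 probes passed, 1204 had an unadjusted p under 0.05 (661 higher, 543 lower), and 1836 passed without WT rosiglitazone replicate 2. In the lists named above, 5 mast cell, 4 PPARG target, 4 interferon and 1 beta-oxidation gene passed when adjusted over the list alone. The PPARG target and inflammatory calls were lost without WT rosiglitazone replicate 2, the brown and beige call without replicate 1 of either vehicle group, and the chromosome 7 call under 8 of 16 alternatives.

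Averaged over treatments, 3 probes differed between genotypes by limma, named after their values were seen. Rtn4, which encodes the membrane protein Nogo, was higher in Fgf21-KO by 2.97 (SE 0.21, adjusted p = 0.0301, n = 4 pools per side) at probe ILMN_1239786, detected on 0 of 4 arrays in each WT group and 4 of 4 in each Fgf21-KO group. Its other two probes had differences of 0.46 and 0.34 (adjusted p = 0.258 and 0.381). Napepld, an enzyme of N-acylethanolamine synthesis, stood at -1.25 (SE 0.09, adjusted p = 0.0301) at probe ILMN_2618526, and at -0.52 (adjusted p = 0.154) at its other probe. Rprml stood at -2.17 (SE 0.17, adjusted p = 0.0303) at its single probe, ILMN_2968147, detected on 4, 4, 1 and 0 of 4 arrays in WT vehicle, WT rosiglitazone, Fgf21-KO vehicle and Fgf21-KO rosiglitazone. At each called probe all 4 Fgf21-KO pools lay on 1 side of all 4 WT pools. The sizes depended on the background step: without correction Rtn4 stood at 1.43, Rprml at -0.97 and Napepld at -0.89. Over all alternatives the Rtn4 call was kept in 10 of 16, the Napepld call in 9 of 17 and the Rprml call in 9 of 16. Mast cell markers were lower in Fgf21-KO (median -0.67, 7 of 7, adjusted p = 4.08e-10, adjusted p = 0.424 with an estimated correlation, fry 0.0137), and mesothelium markers too (median -0.48, adjusted p = 1.36e-04, adjusted p = 0.681 with an estimated correlation). Epithelium markers, a list written afterwards that shares 4 of its 14 genes with the mesothelium list, had a median of -1.10 (adjusted p = 1.36e-10, adjusted p = 0.209 with an estimated correlation). PPARG targets were higher (median 0.15, adjusted p = 0.00890, adjusted p = 0.579 with an estimated correlation), with Plin2 at 0.45 (SE 0.10), and matrix genes too (median 0.16, adjusted p = 0.0371, adjusted p = 0.681 with an estimated correlation). Clock genes were lower (median -0.28, 8 of 13 lower and 5 higher, adjusted p = 0.0371, adjusted p = 0.579 with an estimated correlation), with Per2 at -0.70 (SE 0.13) and Dbp at -0.88 (SE 0.17). Interferon genes were lower as well, at -0.11 (adjusted p = 0.0371, adjusted p = 0.579 with an estimated correlation).

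For genotype over both treatments 1931 probes had an unadjusted p under 0.05 (867 higher, 1064 lower) and 73 an adjusted p of 0.1 or less. In the called lists, 6 mast cell, 3 mesothelium, 2 PPARG target, 7 clock (6 lower, 1 higher), 2 interferon and 1 matrix gene passed when adjusted over the list alone. The macrophage gene Cd163 stood at -0.69 (SE 0.11), the ERK response genes Phlda1 and Dusp4 at 0.78 (SE 0.13) and -0.46 (SE 0.09), and the chemokine gene Cxcl10 at 1.37 (SE 0.34). Without WT rosiglitazone replicate 1, 123 probes passed, and 2755 without replicate 2, whereas 0 or 1 passed without any other single pool. The clock call was lost under 11 and the interferon call under 12 of 16 alternatives, the matrix call under 8, the PPARG target call without WT or Fgf21-KO rosiglitazone replicate 2, and the mesothelium call without WT rosiglitazone replicate 2.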

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

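The tests of tissue admixture, of a response to rosiglitazone in the pool that stood apart, of the share of adipocytes and of strain segments were chosen after the results were seen, whereas the others in this part were set beforehand. Gene lists whose response to rosiglitazone differed between genotypes by the test of the interaction are given first, as the median of Fgf21-KO response minus WT response (log2). The values were 0.11 for PPARG targets, 0.27 for beta-oxidation, 0.13 for oxidative phosphorylation, 0.13 for the tricarboxylic acid cycle, 0.18 for inflammatory genes, 0.16 for endothelial markers and 0.28 for interferon response genes. They were -0.23 for fatty acid and triglyceride synthesis, -0.40 for mesothelium markers and -0.63 for mast cell markers. None of the 10 differences passed with an estimated correlation (lowest adjusted p = 0.482), and without WT rosiglitazone replicate 2 none passed.

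WT rosiglitazone replicate 1 stood apart from the other 7 pools. A response to rosiglitazone in WT was argued against as the cause of the full shift, for the smooth muscle genes only. In the other WT rosiglitazone pool they lay 0.243 (MAD 0.295) above the pools of the other groups, against 2.28 for replicate 1 above the other 7. There 13 of 17 were higher, so a weaker shift the same way is not excluded. For the epithelium genes such a response stays open. In that other WT rosiglitazone pool they lay 1.03 (MAD 0.788) above the pools of the other groups, with all 14 higher, against 1.74 for replicate 1. Epithelium in both dissections would give the same. Smooth muscle or epithelium dissected with the fat is a candidate explanation that these values go with: Actg2 stood at 13.97 in this pool against 6.08 to 8.75 in the others and Tpm2 at 12.48 against 7.71 to 8.96, though Synpo2 (7.27 against 8.40 to 9.10) and Cald1 (5.41 against 5.94 to 6.65) were lower, 12 of the 17 smooth muscle genes exceed the median gene in this fat, and 4 of 14 epithelium genes are also in the mesothelium list. Signal lost at single probes stays open: 105 bright probes were lower by 2 or more in this pool against 0 to 3 in each other pool, and over 60 such cases the other probes of the gene had a median of -0.891, between the bounds of -0.5 and -1 set beforehand.

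Oxidative and PPARG target lists passed as responding more to rosiglitazone in Fgf21-KO than in WT by camera, but not with an estimated correlation (adjusted p = 0.488) or without WT rosiglitazone replicate 2. That WT rosiglitazone replicate 1 alone made this difference was argued against for oxidative phosphorylation only. The median of that list was 0.209 without this pool, against 0.134 with all pools. This pool stood higher for that list than WT rosiglitazone replicate 2 (0.157 and -0.003, list medians relative to the other pools). The rise without it therefore follows from its level and is no separate evidence. PPARG targets were not part of this test. A lower share of adipocytes in the WT rosiglitazone pools could not be settled, since 12 other adipocyte genes differed by -0.0128 under rosiglitazone and the PPARG targets outside the adipokine list by 0.205, within the spread of those genes (0.325). Loss of Fgf21 as the cause could not be settled either: the list was higher in the Fgf21-KO pool in 2 of 4 pairings of pools, with medians from -0.06 to 0.13, and the WT rosiglitazone pools differed by 0.112. Both spreads were brought in after the values were seen, and by the bounds as first written both explanations would have been counted against.

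Genes that differed between genotypes averaged over treatments lay near each other: of 66 at an adjusted p of 0.1 or less, 7 (Pik3r3, Mutyh, Cited4, Fhl3, 9930104L06Rik, Gnl2 and Oscp1) lay among 100 neighbouring tested genes on chromosome 4, where 10000 random draws gave a median of 4 (permutation p = 0.0023). Strain segments carried along in the mixed background are a candidate explanation that stays open, a hypothesis found and tested on the same data, with the window and threshold chosen after the cluster was noticed. In 3 of the 7 the difference lay mostly under rosiglitazone (vehicle and rosiglitazone: Oscp1 -0.14 and -1.11, Cited4 -0.73 and -2.81, Mutyh -0.42 and -1.19). Cited4 was detected on 2 of 4 arrays of WT vehicle, 4 of 4 of WT rosiglitazone and 0 of 4 in each Fgf21-KO group. Its differences are therefore limited by the background. Among the 49 genes with an unadjusted p under 0.05 and the same sign under each treatment the largest number was 4, against a random median of 3 (permutation p = 0.378). Next to Fgf21 itself, 0 of 32 tested genes were in the set, against 0.221 expected at its share over all genes and 2.24 at the density of the cluster (probability of 0 there 0.0981), so this count decides nothing. Loss of Fgf21 acting on these genes was not tested apart from strain segments, because the genotype and such segments go together in this design.

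For genotype, 1 of the 35 splits of the 8 pools into 4 and 4 called as many probes as the real one. That was the real split itself, with 13 probes in a plain model of 2 groups, and the highest other split called 1. With 35 splits, 1 is the fewest this test can return. The real split thus stood out among the splits, but chance was not excluded for that count. Nor can the count tell genotype from a chip or run that goes with it, since bead numbers also separated the genotypes. The main model called 3 probes. For rosiglitazone the real split called 0 probes, so all 35 splits called as many by construction and this count says nothing about chance, and the highest other split, with 13, was the genotype split.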

How the results depend on the processing

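The fit without both pools that stood apart and the fit with weights were chosen after the data were seen. In the order rosiglitazone in WT, rosiglitazone in Fgf21-KO, genotype under vehicle, genotype under rosiglitazone, interaction, rosiglitazone over both genotypes and genotype over both treatments (the latter called averaged), the numbers of probes called were 0, 0, 0, 0, 0, 0 and 3. The cause of each move below was not tested unless stated. Counts that moved were 2, 3, 1 and 6 (WT response, genotype under vehicle, under rosiglitazone and averaged) without background correction, with the deposited normalized values and with the series matrix values alike. In the same order they were 1, 2, 5 and 13 (6 higher, 7 lower) with an offset of 50, 1, 2, 1 and 9 for probes detected on all 16 arrays, and 2, 3, 13 and 39 with a trended, robust variance. Median scaling gave 1 for WT, 57 for genotype under rosiglitazone and 26 averaged (5 higher, 21 lower), and it moved the median of all probes to -0.17 and -0.11 in those genotype contrasts, so its excess of lower calls is relative to that shift. Genotype averaged gave 5 without the probe filter, 0 with the technical repeats only, 15 without both pools that stood apart, and 1 with weights, under which genotype under vehicle gave 9. The weights come out equal within a group of 2 pools and so weigh groups (1.41, 0.284, 1.75 and 1.43). With only 2 groups in the fit, genotype under rosiglitazone gave 2. All 16 arrays with the pool as a random block (consensus correlation 0.450) gave 61, 13, 41, 666, 22, 20 and 535, by a construction that adds arrays and not mice.

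Replicate number as a block gave 0 for genotype averaged. Across the 6 pairs of groups, the deviations of equally numbered pools correlated from -0.10 to 0.27, with 2 above 0.1, so pairing by number has little footing in the values.

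Leaving out 1 pool at a time gave 0 to 2702 probes for rosiglitazone in WT, 0 to 0 in Fgf21-KO and for genotype under vehicle, 0 to 3391 for genotype under rosiglitazone, 0 to 1702 for the interaction, 0 to 1836 for rosiglitazone averaged and 0 to 2755 for genotype averaged. Each highest count came without WT rosiglitazone replicate 2, where WT rosiglitazone replicate 1 stands alone and is assumed to vary like the other pools. Lists passing ranged from 1 to 5, 4 to 8, 2 to 7, 1 to 7, 0 to 11, 7 to 11 and 1 to 7 in the order above. The agreement of the rosiglitazone response between genotypes ranged from -0.0242 to 0.123, and was -0.00847 with the first arrays only, where a move of under 0.1 without a change of sign was counted as none. The oxidative phosphorylation median for genotype under rosiglitazone ranged from -0.0703 (without WT rosiglitazone replicate 2, reversed) to 0.0939, and the mesothelium median for the interaction from -0.769 to 0.0178 (without Fgf21-KO rosiglitazone replicate 2, reversed).

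Fgf21, genotype over both treatments, ranged from -2.64 to -2.04 when 1 pool was left out. It passed the threshold with median scaling (-2.39, adjusted p = 0.0308), without both pools that stood apart (-2.14, adjusted p = 0.0371) and without either WT rosiglitazone pool, and over its 16 alternatives the adjusted p ran from 0.00117 to 0.340.

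With an estimated correlation 0, 0, 0, 0, 0, 0 and 0 lists passed, and with fry 2, 0, 1, 1, 0, 2 and 1. Over all alternatives, 570 list values kept direction and side of the threshold, 210 fell short of it, 2 moved and 2 reversed. Of the values of named genes 2095 were the same, 136 moved, 21 came to pass and 21 fell short, and of counts and agreement values 216 were the same, 88 moved and 4 came to pass. Signal over background limits dim probes: under the 4 scalings 17 of 532 panel values changed sign, 0 of them where the size exceeded 0.3.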

Other observations

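The values in this part are given without explanation, and the lists for smooth muscle, liver, epithelium and ciliated cells were tested only after they had been seen to stand out. Other gene groups of the fat pad showed no passing difference by camera in any of the 7 contrasts. For genotype averaged over treatments, FGF21 receptor and ERK response genes had a median of 0.27 (adjusted p = 0.430), SUMO pathway genes 0.04 (0.402), adipokines and insulin signalling genes -0.03 (0.770), lymphocyte markers 0.09 (0.564), cell cycle genes 0.03 (0.111), heat shock and immediate early genes 0.07 (0.865) and skeletal muscle markers 0.00 (0.696). For rosiglitazone averaged over genotypes the medians in the same order were -0.01, -0.06, -0.01, -0.13, 0.06, 0.03 and 0.14. Camera's direction and the median differed in sign for several lists that did not pass, among them adipokines in both averages, cell cycle genes for rosiglitazone averaged, and mesothelium and lymphocyte markers in the WT response, at -0.08 and 0.14. Epididymis epithelium and red blood cell markers, with 4 tested genes each, were too few to test and had genotype medians of -0.39 and 0.34, with Wfdc2 of the epididymis list at -1.49 (SE 0.21).

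The lists written afterwards (smooth muscle, epithelium, ciliated cells and liver) held 17, 14, 8 and 17 tested genes. In Fgf21-KO their medians for rosiglitazone were 0.16 (camera adjusted p = 0.754), -0.21 (0.155), -0.07 (0.757) and -1.82 (3.28e-07), with an adjusted p of 0.814 or higher with an estimated correlation. In WT that of liver was 0.25 (0.540).

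The authors' deposited table of 2661 entries, made by the VAMPIRE test on all 4 arrays of a group, called 485 for rosiglitazone in WT (387 above 1, 98 below), 309 in Fgf21-KO (102 above, 207 below) and 829 for genotype under vehicle (81 above, 748 below). Its WT means matched those of the non-normalized signals for 2462 entries and those of the normalized signals for 0, within a relative tolerance of 5e-04. Of 780 matched genotype calls, 708 (90.8%) lay below 1 in that table, and 708 were lower in Fgf21-KO after quantile normalization too, with a median log2 difference of -0.33. These calls were chosen on the same arrays, so the equal count is no separate support for their direction. Over all probes tested here under vehicle, 320 were higher and 335 lower at an unadjusted limma p under 0.05. The mean signal ratio of Fgf21-KO vehicle over WT vehicle was 0.853 over all probes, and the median signal ratio was 0.820 over probes detected on no array. In that table the genotype ratio of Fgf21 was 0.406, the rosiglitazone ratios of Ucp1 were 1.528 in WT and 1.521 in Fgf21-KO, those of Cidea 1.583 and 1.329, and that of Scd1 in Fgf21-KO 0.719.

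Probes of 1 gene did not always move together. The brightest probe of Pparg had a rosiglitazone difference of -0.21 in WT, and its other two probes -1.43 and -1.51, with -0.01 for each of these in Fgf21-KO. For Adgre1 the 3 probes stood at 0.02, -1.10 and 0.17 in WT.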
